A study of Mus musculus with 6 samples.

How the data were processed

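RNA was measured in splenic CD3+ T cells of F1 female mice, either on day 0 without stimulation or on day 2, after 48 h with plate-bound anti-CD3 (1 µg/ml) and soluble anti-CD28 (10 µg/ml), with 3 biological replicates per group as labelled. The cells were isolated with enrichment columns, and RNA libraries were made with a stranded total RNA ligation kit that removes ribosomal RNA, per the submitters' protocol notes. The mothers were C57BL/6 (mus) and heterozygous for a deletion of Xist, the RNA that coats and silences the inactive X. The fathers were M. m. castaneus (cast). In daughters that inherit the deletion the mus X is the active one in every cell and the cast X is the inactive one, so cast reads of X-linked genes come from the inactive X.

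The submitters' processing notes name STAR 2.7.1a and featureCounts, without a version of the latter, and the mm10 build. The 1st deposited table holds RPKM (reads per kilobase of gene and per M (mega) reads, per the file headers) for both alleles together. The 2nd deposited table holds whole-number counts per gene of reads assigned to the mus or to the cast allele, per the file headers. How reads were assigned to an allele, which gene annotation and lengths were used, whether featureCounts was strand-specific and which reads entered the RPKM denominator are not given in the sources used here. Of the 49671 genes in the tables, 49412 (99.5%) matched GENCODE M21 by identifier, all of them on the same chromosome, and positions below come from that annotation on mm10. Low RPKM values fell on multiples of 0.5 read steps in 88.7% to 89.7% of cases within a tolerance of 0.02 steps. These steps correspond to 12.7 M to 30.4 M reads per library.

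Allelic depth ran from 9.61 M to 20.2 M reads per library, of which 187532 to 383355 fell on X-linked genes other than Xist. The unstimulated libraries had 11.9 M, 9.61 M and 11.7 M allelic reads and the stimulated libraries 14.9 M, 18.04 M and 20.2 M. The cast share of autosomal reads was 49.3% to 49.4% in the 6 libraries, close to equal parts. No allelic reads were assigned to the mitochondrial genome. Shares of single libraries carry 95% exact Clopper-Pearson intervals, and a share of 0 is given with the upper limit that a count of 0 allows (3 counts of the total). Intervals and floors cover counting error only.

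Diploid expression was compared between groups with limma 3.58.1 (moderated test with a trend, two-sided) in R 4.3.3 on log2(RPKM + 1), for genes with an RPKM of at least 1 in at least 3 libraries. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with 0.05 as the threshold. Log2 fold changes are differences of mean log2(RPKM + 1), and folds are ratios of mean RPKM. Gene lists were compared with the remaining genes with limma's camera at a preset correlation between genes of 0.01, and again with an estimated correlation. The lists were naive and quiescent T cell genes, activation receptors and transcription factors, cytokines with chemokines and cytotoxic effectors, NF-kB components and targets, X inactivation factors, cell cycle, glycolysis, ribosome biogenesis, interferon response, X-linked immune genes, known mouse escape genes, maternally and paternally expressed imprinted genes, mitochondrially encoded genes, Y-linked genes, and markers of T cells, B cells, myeloid cells, NK cells, and erythroid cells with platelets.

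A changed cast share was tested with edgeR 4.0.16 (quasi-likelihood, two-sided) as the interaction of allele and group, with 1 term per library, for genes with at least 30 allelic reads over the 3 libraries of each group. Adjusted p-values are Benjamini-Hochberg values over the X-linked genes tested, and separately over autosomal genes. Levels of cast and of mus transcripts of X-linked genes were compared with edgeR (quasi-likelihood) with library sizes from all allelic reads and TMM factors of the summed counts, for genes with at least 10 reads of that allele. A gene was called expressed from the inactive X in a group when each of its 3 libraries had at least 20 allelic reads and a cast share of at least 10%. Calls were compared over the genes with at least 20 allelic reads in all 6 libraries. The summed cast share of X-linked reads was compared with an exact two-sided permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Xist was left out of the summed share, the calls and the test of a changed share on the X, and kept in the test of cast and mus levels.

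The labels number the replicates alike in both groups without saying that equal numbers are the same animal. Across 9043 autosomal genes with at least 50 allelic reads per library, the log2 ratios of cast to mus, centred within each group, correlated at 0.28, 0.30 and 0.18 between libraries of the same number. Diploid log2 expression, centred alike, correlated at 0.00603, 0.0611 and 0.0908. These are correlations across genes, which are not independent replicates. Equal numbers therefore share an allelic pattern, which does not show that they are the same animal. Each test was also fitted with the number as a block, whose counts stand beside the main counts, with values for single genes or lists where the block changed the call.

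The comparisons, tests, thresholds, lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes of the diploid comparison are the 8 largest rises and the 8 largest falls past the test with a mean RPKM of at least 5 in the higher group and no overlap between groups, leaving out pseudogenes, receptor segments and genes with provisional names, with up to 4 members of each list that passed the test and changed most, and Xist, Nfkb1, Rela, Rel, Il2ra and Cd3e. Named allelic genes are up to 10 X-linked genes per direction past the interaction test, genes called in 1 group alone, the 4 known escape genes with most allelic reads, up to 6 X-linked immune genes with the highest cast share, and up to 8 genes per direction with the largest change of cast level and at least 20 cast reads over the higher group. Some results that this rule selects are not reported here. Other genes named below were chosen after their values were seen.

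The alternatives tried were other pseudocounts, other filters, quantile normalisation and median centring of log2 RPKM, edgeR and DESeq2 1.42.0 on summed allelic counts, DESeq2 for the allelic tests, other read minimums and share thresholds, a correction for the autosomal cast share, adjustment over all genes, library sizes without TMM factors, the replicate block, and leaving out each library in turn. The pipeline was tested on simulated data with known changes. The diploid test recovered 72.0% of 100 genes changed by 1 on the log2 scale and 100% of 100 changed by 2, with 0.0996% of unchanged genes called. The interaction test recovered 67.0% and 94.0% of autosomal genes at these sizes. For X-linked genes changed by 2 it recovered 19.6% of those with a cast share under 1%, 62.5% of those at 1% to 10% and 88.0% of those at 10% to 90%. The test of cast levels recovered 86.7% of 60 genes changed by 2, but with library sizes alone, without the TMM factors of the main test. All simulations used assumed dispersions. The changed autosomal genes were drawn from those with intermediate cast shares. In the diploid simulation far fewer genes changed than passed in the data. These rates therefore need not hold for the tests as run. Reads were not used here, so allele assignment could not be redone.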

Results

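RNA of splenic CD3+ T cells was sequenced from F1 females of a cross in which the paternal cast X is the inactive one. There were 3 unstimulated libraries (day 0) and 3 libraries after 48 h of anti-CD3 and anti-CD28. These antibodies trigger the T cell receptor and the costimulatory receptor CD28. Expression of 49671 genes was given as RPKM, and allelic read counts split the reads of each gene into mus and cast. Allelic reads numbered 11.9 M, 9.61 M and 11.7 M in the unstimulated libraries and 14.9 M, 18.04 M and 20.2 M in the stimulated ones. The title of the series asks about NF-kB signalling, the localisation of Xist RNA and the maintenance of X inactivation after T cell activation. The data address this at the level of transcripts, through expression and through the share of reads from the inactive X.

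The 1st comparison asked which genes changed with stimulation, in reads of both alleles together. Il24, a cytokine gene, was listed at 0 RPKM in all unstimulated libraries and reached 326 ± 23.2 (SD, n = 3). Gzmb, which encodes a cytotoxic granule protease, rose from 18.4 ± 2.25 to 2090 ± 51.0 RPKM (SD, n = 3 each, log2 fold change 6.76). Il2ra, the alpha chain of the interleukin-2 receptor, rose from 4.96 ± 0.25 to 284 ± 13.3 RPKM (log2 5.58). The other large rises were Lif (log2 5.86), Il13 (5.65), Ccr8 (5.23), Gzmc (5.22) and Egln3 (5.16), 3 cytokine or receptor genes, a granzyme and an oxygen-sensing hydroxylase. The largest falls included Klf2, a transcription factor of quiescent T cells, from 314 ± 25.6 to 1.25 ± 0.17 RPKM (log2 -7.13), and Fosb, an early response factor, from 112 ± 2.82 to 0.149 ± 0.0429 RPKM (log2 -6.62). The remaining falls named by the rule were genes of granulocytes, macrophages and plasma cells, namely Lyz2 (log2 -8.69), S100a9 (-8.52), S100a8 (-8.19), Jchain (-7.40) and Lyz1 (-7.39), with Retnlg, which fell from 111 ± 40.0 RPKM and was listed at 0 in all stimulated libraries.

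Of 13288 genes tested with limma (Benjamini-Hochberg), 10642 (80.1%) passed, with 4148 higher and 6494 lower after stimulation. At a change of at least 2-fold there were 1652 higher and 3248 lower genes. The groups did not overlap for 11091 genes (83.5%), where chance gives 10%. With the replicate number as a block 10464 genes passed. The balance of rises and falls depended on scaling, since the median gene moved by -0.24 on the log2 scale as deposited, by 0.02 after median centring and by 0.04 after quantile normalisation. Median centring gave 5432 higher and 5206 lower genes and quantile normalisation 5394 and 4878.

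Quiescence genes fell and activation genes rose. Of 22 naive and quiescent T cell genes 21 fell and 1 (Satb1) rose, also when adjusted over the list alone, among them Klf2, Klf3 (log2 -4.74), Tsc22d3, a glucocorticoid-induced regulator (-4.45), and S1pr1, a receptor for exit from lymphoid tissue (-4.34). Of 29 activation receptors and transcription factors 22 rose and 7 fell, in both adjustments. Il2ra, Tnfrsf9 (log2 4.69), Tnfrsf4 (4.48) and Lag3 (4.19), surface receptors of activated T cells, rose most, while the early markers Cd69 (-2.95), Egr1 (-0.65) and Egr3 (-1.27) were among those that fell. Of 21 tested genes for cytokines, chemokines and cytotoxic effectors 16 rose and 5 fell, adjusted over the list alone as well, and the chemokine gene Ccl5 fell from 115.4 ± 5.73 to 2.67 ± 0.22 RPKM (SD, n = 3 each). All 3 lists passed camera, with limma adjusted p-values of 8.4e-06, 8.4e-06 and 0.00014. With an estimated correlation none of them passed (adjusted p = 0.515, 0.203 and 0.185).

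Genes of growth and division rose together. Of 40 cell cycle genes 37 rose and 1 fell, all of them also when adjusted over the list alone, with Cdc20 (log2 3.43), Aurkb (3.43), Top2a (3.36) and Cdk1 (3.31) rising most. Unstimulated replicate 3 stood apart here, with a mean log2 level of 3.78 over these genes, against 2.55 and 2.56 in the other unstimulated libraries. Of 19 glycolysis genes 18 rose and none fell, also when adjusted over the list alone, including Tpi1 from 16.3 ± 4.94 to 326 ± 13.9 RPKM (SD, n = 3 each), Pgk1 (log2 4.11), Hk2 (3.79) and Gapdh (3.27). All 22 ribosome biogenesis genes rose in both adjustments, with Npm1 (log2 1.85), Nolc1 (1.63), Mybbp1a (1.55) and Rrp12 (1.46) first. Camera gave adjusted p-values of 2.5e-09, 6.7e-10 and 4.4e-09 for these 3 lists, against adjusted p = 0.515, 0.185 and 0.408 with an estimated correlation.

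The NF-kB list, which bears on the question of the series, split. Of its 26 genes 11 rose, 11 fell and 4 did not pass, with the same counts when adjusted over the list alone, against 12 and 7 after median centring and 12 and 9 after quantile normalisation. Nfkb1, the gene of the p105/p50 subunit, rose from 22.3 ± 1.09 to 47.8 ± 2.89 RPKM (SD, n = 3 each, log2 1.07), Rel rose by 0.51 on the log2 scale, and Bcl2l1, an anti-apoptotic target, rose by 2.05. Nfkbiz (log2 -2.49) and Ikbke (-2.28), a nuclear regulator and a kinase of the pathway, fell. Rela, the gene of the p65 subunit, had a log2 fold change of -0.33 (limma adjusted p = 0.0016), which did not pass after median centring (-0.07) and was positive on summed allelic counts with edgeR (0.08) and DESeq2 (0.05), so its direction is unsettled. The list's median was -0.14 and its mean -0.15 while limma's camera placed it upward without passing (adjusted p = 0.648), and median centring turned the median to 0.12.

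X inactivation factors, proteins and RNAs that act with Xist, also went both ways, with 13 of 32 up, 12 down and 7 not past the test, in both adjustments, against 19 up and 8 down after median centring and 15 and 9 after quantile normalisation. Ezh2, the methyltransferase of Polycomb complex PRC2, rose from 6.34 ± 3.11 to 32.8 ± 1.30 RPKM (SD, n = 3 each, log2 2.28). Pcgf5 of PRC1 (log2 1.501) and the DNA methyltransferase gene Dnmt1 (1.37) also rose, and Ythdc1, a reader of methylated RNA, fell by 1.23. Xist itself was at 97.9 ± 14.6 RPKM unstimulated and 78.0 ± 4.63 stimulated (log2 -0.32, limma adjusted p = 0.034), a difference that did not pass after median centring (-0.06) and was positive on summed allelic counts with edgeR (0.11) and DESeq2 (0.08). It also did not pass without any 1 of the stimulated replicates (adjusted p = 0.108, 0.0631 and 0.0627 without replicates 1, 2 and 3). The list's median was -0.03 and its mean 0.13, camera placed it upward without passing (adjusted p = 0.202), and the median turned to 0.23 after median centring and to 0.06 after quantile normalisation.

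Interferon response genes fell, with 18 of 24 down, 3 up and 3 not past the test in both adjustments, among them Rtp4 (log2 -3.12), Ifit3 (-3.01), Irf7 (-2.67) and Rsad2 (-2.40). Camera gave an adjusted p of 0.0091, and with an estimated correlation adjusted p = 0.515. X-linked immune genes showed 25 falls, 8 rises and 7 members not past the test out of 40, in both adjustments. Those that changed most were Tsc22d3 (log2 -4.45), Cybb, a phagocyte oxidase subunit (-3.71), Tlr13 (-2.95) and Arhgap4 (-2.66). Camera did not pass for this list (adjusted p = 0.138). Cybb and Tlr13 are also expressed in myeloid cells, and the myeloid markers moved the same way as both lists, with falls of all 17 tested genes and a median log2 of -3.74, as did the NK cell markers, with falls of 10 of 11 and a median of -3.19. Of 12 tested known escape genes, which are expressed from the inactive X in many mouse tissues, 3 rose, 6 fell and 3 did not pass, in both adjustments, but 5 rose and 2 fell after median centring and 5 and 3 after quantile normalisation. Eif2s3x, a translation initiation factor gene, rose from 20.3 ± 1.77 to 59.99 ± 2.55 RPKM (SD, n = 3 each), Utp14a rose (log2 1.01), and the demethylase gene Kdm6a fell (-0.73). Mid1 had a log2 value of -0.61, which was 0.09 after quantile normalisation. The list's median was -0.28 and became 0.06 after quantile normalisation, while camera placed the list upward without passing (adjusted p = 0.812).

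Of the imprinted genes, all 7 tested paternally expressed genes fell in both adjustments, with Peg13 (log2 -2.61), Zrsr1 (-1.79), Mcts2 (-1.43) and Airn (-1.11) first (camera adjusted p = 0.0185, and adjusted p = 0.268 with an estimated correlation). Of 2 tested maternally expressed genes Gnas rose (log2 0.78) and Igf2r had a value of -0.30, which did not pass after median centring (-0.04). These 2 were too few for camera. Of 10 tested mitochondrially encoded genes 2 fell, mt-Rnr1 (log2 -1.23) and mt-Cytb (-0.55), none did when adjusted over the list alone, and camera did not pass (adjusted p = 0.812). The change of mt-Cytb did not pass after median centring (-0.29) or on leaving out any library other than unstimulated replicate 1 (adjusted p = 0.0851 to 0.137). Unstimulated replicate 1 stood apart for this list, with a mean log2 level of 6.78 against 7.92 and 8.04 in unstimulated replicates 2 and 3 and 7.09, 6.85 and 7.09 in the stimulated ones. No Y-linked gene of the list reached the expression needed for testing.

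Markers of other cell types were lower in the stimulated libraries. Of 19 T cell identity genes 4 rose, 8 fell and 7 did not pass (4 and 7 when adjusted over the list alone, 7 and 4 after median centring, 4 and 10 after quantile normalisation), led by Cd3g (log2 -1.20), Cd3e, which fell from 75.2 ± 8.33 to 40.1 ± 2.63 RPKM (SD, n = 3 each), Cd2 (0.84) and Cd6 (0.80). The median of this list was -0.14, turned to 0.12 after median centring, and camera placed it upward without passing (adjusted p = 0.826). B cell markers fell for 16 of 17 genes, including Cd79a (log2 -3.62), Fcrla (-3.57), H2-Aa (-3.37) and Cd74 (-3.23). Myeloid markers fell for all 17 tested genes, including Lyz2, S100a9, S100a8 and Csf3r (-6.27). NK cell markers fell for 10 of 11 genes, including Tyrobp (log2 -5.00), Ncr1 (-4.79), Klra8 (-3.89) and Klra9 (-3.43), while Gzma rose. Erythroid and platelet markers fell for 8 of 10 genes, including Hba-a2 (log2 -5.78), Hba-a1 (-5.66), Hbb-bt (-5.52) and Hbb-bs (-5.31). These counts were the same when adjusted over the list alone. Camera adjusted p-values were 0.0018, 8.4e-06, 0.0023 and 0.132 for the B cell, myeloid, NK cell and erythroid lists (for the last 0.0482 with the replicate block and 0.0195 without unstimulated replicate 1), and with an estimated correlation adjusted p = 0.587, 0.515, 0.515 and 0.759. Of the tested markers 9 of 17 B cell, 3 of 17 myeloid, 7 of 11 NK cell and none of 10 erythroid genes still reached an RPKM of 1 in all 3 stimulated libraries.

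Levels of these markers also varied between the unstimulated libraries. Unstimulated replicate 3, which stood apart for cell cycle genes, had mean log2 levels of 5.08 over B cell, 5.78 over myeloid and 5.71 over erythroid genes, against 4.55, 5.03 and 2.71 in replicate 1 and 4.25, 5.22 and 4.57 in replicate 2. Without it 11023 genes passed. In all, 11 of 18 lists passed camera, 5 upward and 6 downward (12 with the replicate block), and 0 passed with an estimated correlation.

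**Figure D1:**
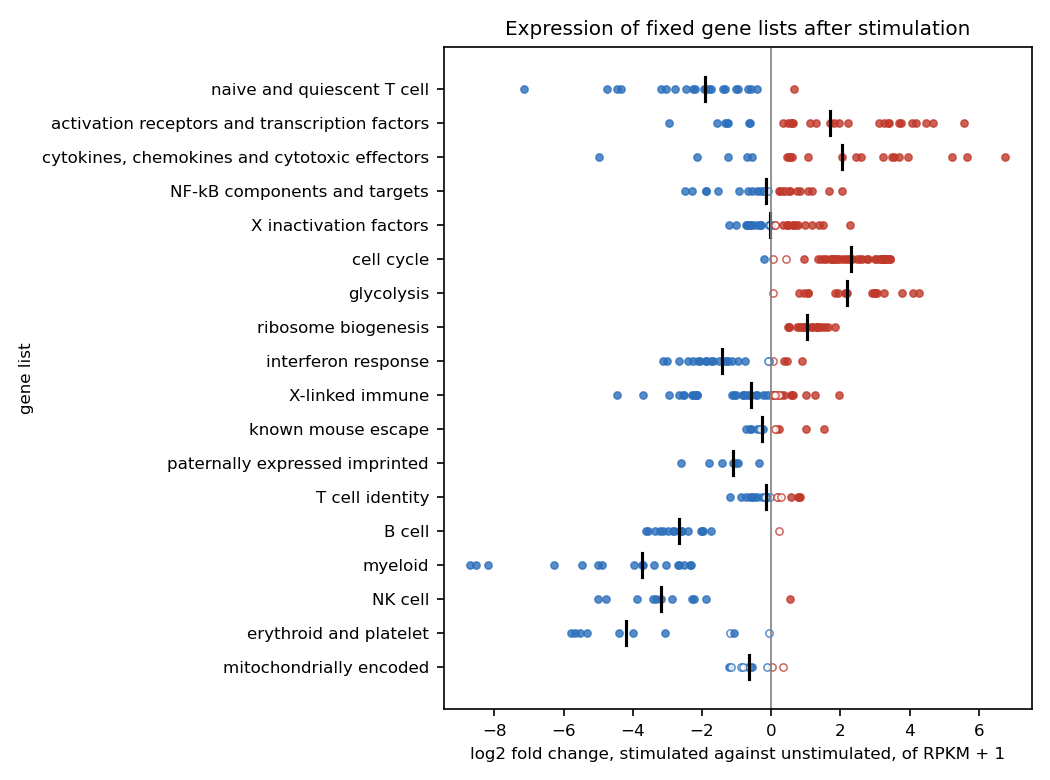
Log2 fold change of RPKM + 1 (horizontal axis, stimulated against unstimulated, n = 3 each) for each tested gene of the lists with more than 2 tested genes (vertical axis), where filled points passed the limma test, open points did not, and black bars are list medians. Medians ran from -4.19 for erythroid and platelet genes to 2.29 for cell cycle genes, and the near-0 medians of the NF-kB and X inactivation lists change sign after median centring.

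X-linked expression as a whole was then set against that of autosomes, to see whether the X moved as a unit. Of 387 tested X-linked genes 127 rose and 160 fell, with a median log2 fold change of -0.07 against -0.25 for 12870 autosomal genes. The set did not differ from the other genes (camera p = 0.285, and p = 0.801 with an estimated correlation, or p = 0.284 with the replicate block).

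The allelic comparisons asked how far the inactive X contributed transcripts before and after stimulation. Xist (chromosome X, 103460366 to 103483254 on mm10, a noncoding gene) was read from the cast X alone up to a few reads, as the cross implies. Its cast share was 99.92%, 99.92% and 99.93% in the unstimulated libraries and 99.99%, 99.93% and 99.96% in the stimulated ones. Xist made up 73.8% to 78.2% of all cast X-linked reads in the 6 libraries. Its cast RPM (reads per M allelic reads) was 2348 ± 289 unstimulated and 2125 ± 110 stimulated (SD, n = 3 each, exact permutation p = 0.4). The edgeR test of cast levels gave a log2 fold change of 0.16 (adjusted p = 0.0438, or 0.0213 with the replicate block), but -0.14 with library sizes alone (adjusted p = 0.102) and 0.09 with DESeq2 (adjusted p = 0.473), so the direction is unsettled.

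Apart from Xist, few X-linked reads came from the inactive X. The summed cast share was 3.84% ± 0.05 unstimulated and 3.74% ± 0.04 stimulated (SD, n = 3 each), a difference of -0.10 percentage points (exact two-sided permutation p = 0.1, the smallest possible), while autosomes stood at 49.4% ± 0.04 and 49.3% ± 0.05 (exact p = 0.4). All 3 same-numbered differences were negative (mean -0.10, exact p = 0.25, the smallest possible), but replicate 3 was nearly unchanged, at 3.787% and 3.782%. The sign depended on how genes were weighted, since over the 298 genes with at least 20 allelic reads in every library the difference was -0.04 points for summed reads and 0.32 points with equal gene weights in all libraries. Without the known escape list the share went from 2.72% ± 0.06 to 2.19% ± 0.09, and the median gene had a share of 0% in both groups.

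Transcription from the inactive X was confined to a minority of assessed genes. Of 298 X-linked genes with at least 20 allelic reads in every library, 218 (73.2%) had a mean cast share below 1% in both groups. The rule called 32 genes expressed from the inactive X in the unstimulated cells and 33 in the stimulated cells, 30 of them in both. Of the 35 called in either group 8 were pseudogenes, and 5 were read at 90% cast or more in all 6 libraries, where the allele assignment is in doubt. A further 5 had a mean cast share over 60% in at least 1 group, so that the inactive copy would be read more than the active one. Fam220-ps was among them, at 96.3% unstimulated and 100% stimulated. Eif2s3x, at a mean of 54.1% in stimulated cells, was also read more from the inactive copy there. Among the known escape genes with most reads, Kdm5c, a histone demethylase gene (152233020 to 152274535), had cast shares of 29.9% ± 0.76 and 32.8% ± 0.45 (SD, n = 3 each, unstimulated first). Ddx3x, an RNA helicase gene (13280970 to 13294052), had 28.3% ± 2.22 and 32.3% ± 1.60, and Kdm6a (18162575 to 18279936) had 39.8% ± 2.11 and 44.8% ± 1.70. None of these 3 passed the edgeR test of a changed share (adjusted p = 0.198, 0.207 and 0.187), and all 3 did when adjusted over the list alone (adjusted p = 0.0274 each). Of 13 assessed genes of that list 8 were called in each group.

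The genes called in 1 group alone were few. Xlr4a (73074345 to 73082478) and the pseudogene Mdm4-ps were called only in unstimulated cells, at 14.1% ± 2.91 and 22.7% ± 8.01 there against 10.5% ± 1.46 and 19.7% ± 10.39 after stimulation. Neither change passed the edgeR test (adjusted p = 0.620 for Xlr4a). The lowest stimulated library stood at 9.04% for Xlr4a and at 7.69% (2 of 26 reads) for Mdm4-ps. Xlr4b, Gm38020 and Magt1, a magnesium transporter gene (105968084 to 106011906), were called only in stimulated cells. Magt1 had 12.9% ± 3.09 unstimulated and 14.99% ± 2.05 stimulated (SD, n = 3 each), its lowest unstimulated library stood at 9.79% (76 of 776 reads, 95% Clopper-Pearson interval 7.79% to 12.1%), and its change did not pass the edgeR test (adjusted p = 0.694). At a threshold of 20% the counts were 20 and 27, and at 5% they were 45 and 42. Of the 7 genes called in stimulated cells alone at 20%, chosen after their values were seen, Ftx, Gm38020 and 5530601H04Rik passed the edgeR test of a changed share, and Gm14539, Mtcp1, Jpx and Pbdc1 did not (adjusted p = 0.509, 1, 0.509 and 0.0730). Mtcp1 stood at 36.3% and 38.5%, with 1 unstimulated library at 17.9%. Another rule, based on the level of cast transcripts, called 46 and 32 genes.

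X-linked immune genes were mostly silent on the inactive X. Of 34 with enough reads in the stimulated cells 28 had a cast share under 2%. Dock11, a guanine nucleotide exchange factor gene (35888832 to 36076562), had cast shares of 46.0% ± 2.19 and 49.2% ± 3.69 (SD, n = 3 each). Cybb had 22.1% ± 3.57 and 23.8% ± 11.96, the transcription factor gene Elf4 16.996% ± 2.11 and 17.8% ± 0.97, and Arhgap4 11.0% ± 0.95 and 11.0% ± 1.95. Cul4b (38533274 to 38576196) was read from cast at 99.4% ± 0.96 and 100% ± 0, with only 1455 allelic reads where its RPKM would give about 8641, so its share is uncertain. None of these 5 genes passed the test of a changed share, and Phf6 was the 1 immune gene of 36 tested that did (2 when adjusted over the list alone).

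**Figure D2:**
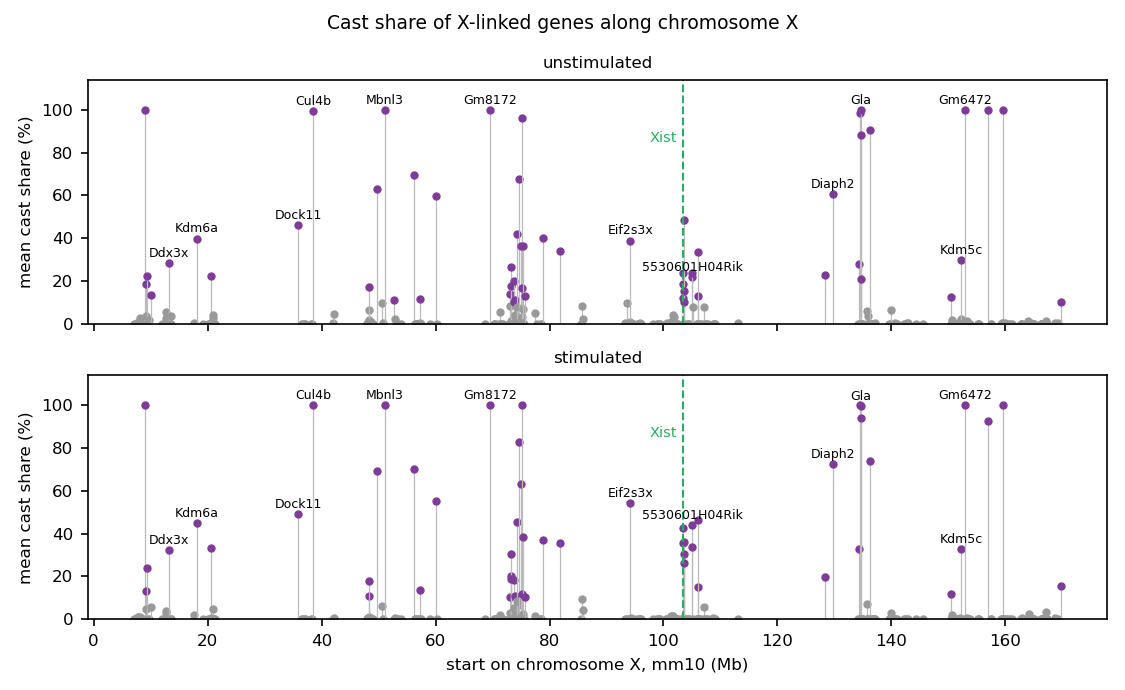
Mean cast share (vertical axis, %, n = 3 libraries) of 362 tested X-linked genes by start position on mm10 (horizontal axis, Mb) in unstimulated (top) and stimulated (bottom) cells, with genes at 10% or more in purple and the position of Xist as a green dashed line. Kdm5c stood at 29.9% and 32.8%, Eif2s3x at 38.8% and 54.1%, and most genes lay near 0 in both panels.

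Whether stimulation changed the cast share of single genes was tested by the interaction of allele and group. Of 362 X-linked genes 5 gained and 6 lost cast share with edgeR (Benjamini-Hochberg over X-linked genes). Eif2s3x (94188707 to 94212862) rose from 38.8% ± 3.27 to 54.1% ± 0.57 (SD, n = 3 each, log2 odds ratio 0.89, adjusted p = 0.00045). Its stimulated libraries stood at 53.6% to 54.7%, above equal parts of both copies. In the X inactivation centre the noncoding Ftx (103560907 to 103623790) rose from 15.2% ± 4.57 to 30.6% ± 4.55 (adjusted p = 0.0113), with Gm38020 (103576426 to 103581101), which lies within Ftx on the same strand, rising from 10.1% ± 0.83 to 26.5% ± 2.77 (adjusted p = 0.00052). The noncoding 5530601H04Rik (105037197 to 105079609) rose from 21.7% ± 7.45 to 43.8% ± 2.47 (adjusted p = 0.0168). Xlr4b (73214333 to 73222453), of a lymphocyte-expressed gene family with near-identical copies, rose from 1.52% ± 1.77 to 20.1% ± 3.67 (adjusted p = 0.00072). Reads shared between copies leave its share, like that of Xlr4a, uncertain. On leaving out 1 library, 5530601H04Rik did not pass without unstimulated replicate 1 or 2 or stimulated replicate 1 or 3 (adjusted p = 0.065 to 0.0995), and Ftx did not pass without stimulated replicate 1 (adjusted p = 0.068).

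Of the 6 genes that lost cast share, all but Armcx1 had under 10% to begin with. Mtmr1, a lipid phosphatase gene, fell from 5.71% ± 0.51 to 1.83% ± 0.34 (SD, n = 3 each, edgeR adjusted p = 0.00052), Tbl1x, a corepressor subunit gene, from 4.99% ± 2.04 to 1.27% ± 0.50 (adjusted p = 0.0014), and Phf6, a chromatin protein gene, from 2.10% ± 0.51 to 0.555% ± 0.13 (adjusted p = 0.0012). Armcx1, Magee1 and Zfx went from 21.0% ± 11.8, 7.99% ± 8.94 and 0.799% ± 0.64 to no cast read, where 0 of 134, 488 and 1999 reads allow shares of up to 2.24%, 0.615% and 0.150% (adjusted p = 0.0438, 0.0346 and 0.0346). These 3 did not pass on leaving out any library other than unstimulated replicate 3 (adjusted p = 0.0543 to 0.191), Magee1 did not pass with DESeq2 (adjusted p = 0.147), and Armcx1 did not at a minimum of 10 allelic reads per group (adjusted p = 0.0513).

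The number of such genes was sensitive to the fit. With the replicate number as a block 24 genes passed, 9 higher and 15 lower, including all 11. Without unstimulated replicate 1 or unstimulated replicate 2 there were 7 genes, and without stimulated replicate 1 there were 6. Of the 13 tested genes of the known escape list other than Xist 3 passed, all higher (Eif2s3x, Ftx and 5530601H04Rik), and 9 passed when adjusted over the list alone, 8 with a higher share and Firre with a lower one. Autosomal genes, the background of this test, passed at 10.43% (1300 of 12470, 715 with a higher and 585 with a lower cast share), against 3.04% of X-linked genes, whose low cast shares leave less power. On the X and on autosomes alike, the test does not separate a changed share within T cells from the lower content of other cell types. On the X the cast copy is the inactive, the paternal and the castaneus copy in every library. A response of the castaneus allele to stimulation therefore cannot be told apart from a change of silencing.

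**Figure D3:**
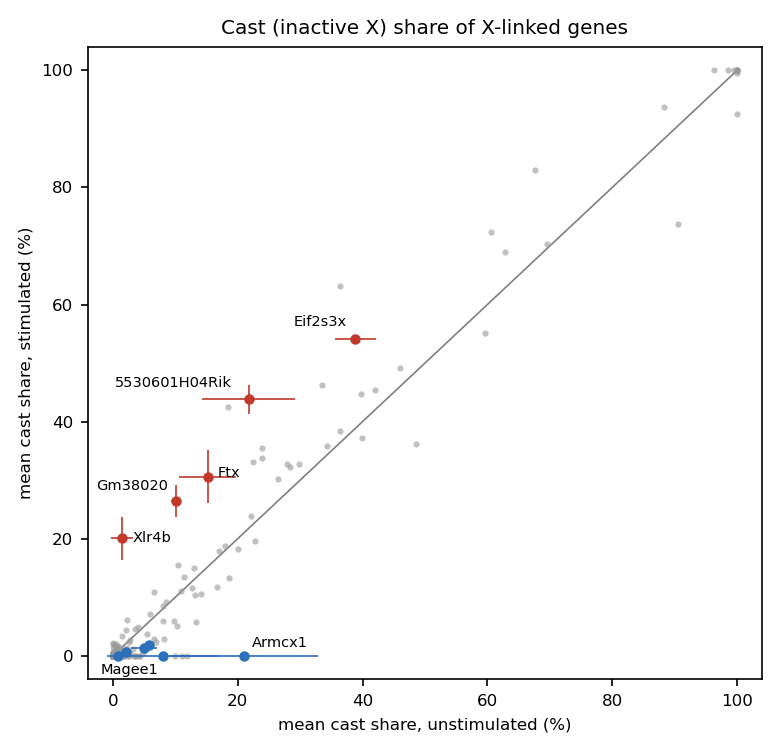
Mean cast share of 362 X-linked genes in unstimulated (horizontal axis, %) and stimulated cells (vertical axis, %), with genes past the edgeR test in red (5 higher) or blue (6 lower), bars of 1 SD (n = 3) on those genes and a line of equality. Xlr4b, at 1.52% and 20.1%, and Eif2s3x, at 38.8% and 54.1%, lie above the line, and Armcx1, at 21.0% and 0%, lies on the horizontal axis.

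The last comparison asked whether the level of transcripts from the inactive X changed, whatever the active X did. Of 152 X-linked genes with at least 10 cast reads 21 rose and 25 fell on the cast X with edgeR (Benjamini-Hochberg). Of these, 7 other than Xist were read at 90% cast or more over all libraries, so that their assignment to the inactive X is in doubt, namely Cul4b, Gm8172, Gm15361, Gla and Gm6472, which rose, and Xkrx and Btk, which fell. Without such genes, an alternative chosen after the values were seen, 16 rose and 23 fell. Eif2s3x rose from 21.7 ± 3.66 to 102 ± 8.01 cast RPM (SD, n = 3 each, log2 2.54) and by 1.66 on the active X. Utp14a, a gene of ribosome biogenesis, rose by 2.23 on the log2 scale, the kinase gene Pim2 by 2.87 (from 0.421 ± 0.09 to 2.54 ± 0.53 RPM), Xlr4b by 3.24, and the pseudogene Gm14539 by 2.65, with Gm9670 at 1.57. Pim2 had cast shares of only 0.530% and 0.727%, unstimulated first, and rose by 2.46 on the active X. Its share did not change past the edgeR test (adjusted p = 0.835), and mus reads assigned to cast could give such a rise. The cast levels of Gm15361 (log2 2.68) and Uba1 (2.02) also passed (adjusted p = 0.0374 and 0.0438) but not with the replicate block (adjusted p = 0.1 and 0.0512). Without 1 library, Gm15361 did not pass lacking unstimulated replicate 2 or stimulated replicate 2 or 3 (adjusted p = 0.147 to 0.188), Uba1 lacking unstimulated replicate 2 or 3 or stimulated replicate 1 or 3 (0.056 to 0.181), and Gm9670 lacking unstimulated replicate 1 or 3 or stimulated replicate 2 or 3 (0.0694 to 0.145). These 3 also did not pass with DESeq2 (adjusted p = 0.117, 0.151 and 0.177), with library sizes alone (0.0753, 0.102 and 0.0874) or with autosomes fitted along (0.0648, 0.104 and 0.109), nor did Uba1 at 30 or more cast reads (0.0523).

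The falls on the cast X named by the rule were the largest with at least 20 cast reads over the unstimulated libraries. Among these named falls, 6 genes ended at no read and 2 at 2 reads. Cxcr3, the gene of a chemokine receptor of effector T cells, went from 54 cast reads over the unstimulated libraries to 0. It was at least 28.8-fold lower against a floor of 3 counts over the group, scaled by allelic library sizes without TMM factors. The same bound was 43.2-fold for Gm5380, 37.9-fold for F630028O10Rik and 14.9-fold for Alas2, an erythroid haem synthesis gene. The bound was 12.3-fold for Cfp, the complement regulator properdin, and 10.7-fold for Cask. Cask did not pass with the replicate block (adjusted p = 0.0736). Gm5380 is a processed pseudogene with a mean cast share of 88.5% in the unstimulated libraries. Its assignment to the inactive X is therefore uncertain. Tsc22d3 went from 58 cast reads to 2, a ratio of 46.4 (95% counting interval 12.3 to 392.2), and Xkrx, which had no mus read to compare in either group, from 106 to 2, a ratio of 84.8 (22.9 to 709). Tsc22d3 fell by 4.46 on the log2 scale on the active X as well. Cast levels of Cxcr3 (adjusted p = 0.077), Tsc22d3 (0.0658), Alas2 (0.0548) and F630028O10Rik, Cfp and Cask (0.0542 each) did not pass without unstimulated replicate 2. The cast level of Cask also did not pass without unstimulated replicate 1 (0.0692).

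The same genes were then compared between the copies. Of the 46 genes that changed on the cast X, 39 were tested on the mus X, 30 had the same direction there and 32 passed there, 27 in the same direction and 5 in the opposite one. Low cast shares can include mus reads assigned to cast, at a rate not measured here. Uba1 had 0.0870% and 0.108% cast, Pim2 0.530% and 0.727%, and Tsc22d3 0.363% and 0.189%, unstimulated first. At Xist 0.0531% of the allelic reads were mus, which bears only on the reverse error, cast reads assigned to mus. Leaving out the genes with a cast share under 1%, a step chosen after the values were seen, 42 genes changed on the cast X (19 up, 23 down), and of 35 tested on the mus X 26 had the same direction and 28 passed, 23 in the same direction and 5 in the opposite one. On the active X 149 of 515 genes rose and 133 fell. The counts were 38 on the cast X (19 up, 19 down) and 274 on the mus X (150 up, 124 down) with the replicate block, and 22 on the cast X without unstimulated replicate 2. With library sizes alone the balance moved towards falls, to 11 up and 32 down on the cast X and 115 up and 174 down on the mus X.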

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

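The tests chosen only after their results were seen were the comparison of cast-only genes between the X and autosomes, the comparison of pseudogenes, and the comparison of neighbours. Values in data outside the comparisons called for a closer look in 3 places. Y-linked reads, of which these females should have none, reached 69 mus reads in stimulated replicate 3, and all 199 Y-linked allelic reads over the 6 libraries came from Erdr1, a gene of the pseudoautosomal region that both sex chromosomes carry. On autosomes, where both alleles should be read about equally, 88 genes had a cast share of at least 90% in all 6 libraries. A further 25 autosomal genes stood apart by at least 25 percentage points of cast share in both libraries of 1 replicate number.

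Of the 298 assessed X-linked genes, 5 were read at 90% cast or more in all libraries, namely the coding genes Cul4b, Mbnl3 and Gla and the processed pseudogenes Gm8172 and Gm6472, which would otherwise pass as transcripts of the inactive X alone. Among coding genes such shares were 1.08% of 277 on the X and 0.370% of 9456 on autosomes, where X inactivation plays no part, and the difference did not pass (two-sided Fisher's exact p = 0.0929), so a strain variant or allele assignment against the reference stays open. Loss of mus reads stays open as well, since Cul4b, Mbnl3 and Gla had fewer allelic reads per read expected from RPKM than most coding X-linked genes, at percentile 11.9 or lower. Processed pseudogenes made up 42.0% of the 88 autosomal cast-only genes against 0.952% of the others (Fisher's exact p = 3.9e-48), so reads of autosomal parent genes are a candidate source for Gm8172 and Gm6472. Expression of the 3 coding genes from the inactive X alone is not excluded by these values and was not tested.

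The 25 autosomal genes that stood apart in 1 replicate number all had a higher cast share in it, with 9 in replicate 1 (7 on chromosome 11 and 2 on chromosome 1), 14 in replicate 2 (chromosome 1, 85894281 to 135752232) and 2 in replicate 3 (chromosome 18). Cxcr4, for example, was read at 99.7% and 100% cast in the libraries of replicate 2 and at a mean of 35.8% in the others. Counting noise is argued against, because libraries of crossed numbers gave 0 such genes. The median autosomal gene of a number deviated by at most 0.0358 percentage points, but every F1 animal of this cross stands near equal parts, so this value does not bear on a swap or a mix of such animals, and a mixed or mislabelled sample stays open. Of the 25 genes 76.0% had another within 2 Mb, as a stretch of the mus chromosome that differs from the reference in that mother's line would give, and this strain variant stays open. No biological explanation was tested, since the design names no difference between the numbers.

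Outside the escape list the summed cast share of X-linked reads was lower after stimulation, at 2.19% against 2.72%. Over the 280 assessed genes outside the list that were not read at 90% cast or more in all libraries, the difference was -0.765 percentage points for summed reads and 0.0345 points upward with equal gene weights in all libraries, so a changed mix of X-linked genes could account for it, with Flna, Arhgap4, Cybb and Elf4 giving fewer cast reads at much the same shares. Loss of other cell types cannot be told apart from this by the test made, in which genes with a diploid log2 fold change of at least 0 gave -0.0350 points, because equal weights left no fall to divide. A change of silencing on the inactive X stays open for single genes such as Mtmr1 and Tbl1x, whose own shares fell, but strain and silencing are confounded there.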

How the results depend on the processing

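The alternatives that left out genes with cast-only reads, pseudogenes or other cell types, weighted genes equally, fitted autosomes along, left out genes by their cast share or required 20 allelic reads in each library were chosen after seeing the data, and where no cause is named the cause was not tested. A 2-fold minimum left 4900 diploid genes by its construction. With an estimated correlation 0 lists passed (adjusted p = 0.515 for naive T cell, cell cycle, interferon, myeloid and NK cell genes, 0.203 for activation, 0.185 for cytokines and glycolysis, 0.408 for ribosome biogenesis, 0.268 for paternally expressed genes and 0.587 for B cell genes), and the replicate block brought the erythroid and platelet list past the threshold (adjusted p = 0.0482, with 0.0195 to 0.165 on leaving out 1 library). Signs turned for Mid1 with quantile normalisation (log2 0.0880), and on summed allelic counts for Xist (0.107 with edgeR, 0.0793 with DESeq2) and Rela (0.0811 and 0.0525), and the cause was not tested. The difference in summed cast share of -0.10 points was 0 for the median gene, -0.53 without the escape list, -0.39 without genes at 90% cast, -0.84 without both and 0.32 with equal gene weights over 298 genes, for which summed reads gave -0.0448. Changed cast shares on the X numbered 24 with the replicate block, 18 with adjustment over all genes, whose threshold is looser because more autosomal genes passed, and 6 to 14 on leaving out 1 library. Levels on the cast X changed for 22 to 50 genes on leaving out 1 library, and a 20% threshold called 20 genes in unstimulated cells. The block changed no other count of genes or lists by over 1.5 times.

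Leaving out 1 library in turn gave 9921 to 11023 diploid genes, 11 or 12 lists, a difference in summed cast share of -0.13 to -0.08 points, 918 to 1047 autosomal genes with a changed share, 247 to 284 genes of the active X and 36 to 39 called genes. For the named genes and lists, 1210 of 1232 alternatives kept direction and side of the threshold for diploid changes (17 no longer passed and 5 turned), 263 of 285 for cast shares (22 no longer passed), 142 of 173 for cast levels (31 no longer passed) and 149 of 162 for lists (11 no longer passed and 2 newly passed). Low cast shares limit the test of a changed share, since changes by 2 on the log2 scale were recovered for 19.6% of simulated X-linked genes with a cast share under 1%.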

Other observations

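The tests of distance to Xist, of neighbouring genes and of matched autosomal genes were chosen only after their results were seen. Allelic balance changed at many autosomal genes as well. At Entpd1, the gene of the ectonucleotidase CD39 (chromosome 19, 40612366 to 40741602), the cast share rose from 29.9% ± 1.08 to 70.7% ± 1.48 (SD, n = 3 each, edgeR adjusted p = 4.2e-08 over autosomal genes), and at Haao, of kynurenine metabolism, from 29.5% ± 3.91 to 75.02% ± 6.40 (adjusted p = 4.4e-06). At Plk2, a stress-induced kinase gene (chromosome 13, 110395046 to 110400844), it fell from 52.0% ± 2.04 to 6.17% ± 1.98 (adjusted p = 4.2e-08), and at Rdm1, a DNA repair gene, from 68.9% ± 2.90 to 23.2% ± 4.57 (adjusted p = 1.5e-06). These 4 are among the 10 with the largest changes of share at 200 or more allelic reads in each group, and the cross has 1 direction only, so strain and parent of origin are confounded. Markers of other cell types were lower after stimulation, so a changed mix of cells was not separated from a change within T cells.

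Most imprinted genes with at least 100 allelic reads were read mainly from the allele of the parent they are known to be expressed from, except Gnas (37.3% and 41.5% cast, unstimulated first), Inpp5f (53.2% and 51.98%) and Mcts2 (43.8% and 54.8%). The paternal cast allele gave 99.8% ± 0.08 and 99.9% ± 0.14 of the reads of Kcnq1ot1 and 98.96% ± 1.80 and 100% of those of Airn (SD, n = 3 each, unstimulated first). Airn is a paternally expressed antisense RNA that represses Igf2r in cis, and it fell with stimulation in the diploid comparison. Igf2r, expressed from the maternal allele, went from 8.56% ± 1.07 to 1.72% ± 0.69 paternal reads (edgeR adjusted p = 2.6e-06 over autosomal genes). Airn (chromosome 17, 12741311 to 12860136) overlaps Igf2r (12682406 to 12769664) on the other strand and fell 4.54-fold in RPKM. As the strand setting of the counting is not given in the sources used here, paternal reads of Igf2r may be reads of Airn, and their share need not measure paternal Igf2r. Whether low shares of a minor allele fall at autosomal genes in general was tested on genes with a mean cast share of 1% to 10%, of which 63.9% of 36 fell (exact binomial p = 0.133), and on the opposite class, where the mus share of 54.4% of 57 genes fell (exact binomial p = 0.597). These counts leave it open whether the fall at Igf2r may be part of a general one.

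Genes called expressed from the inactive X in both groups, leaving out those at 90% cast or more in all 6 libraries, had higher cast shares after stimulation in 23 of 25 cases, with a median rise of 4.76 percentage points. The 25 still hold Fam220-ps (96.3% and 100%, unstimulated first), Hnrnph2 (88.3% and 93.8%) and other pseudogenes. The values below therefore rest in part on genes of doubtful allele assignment. Their mean share was 36.4% ± 1.52 unstimulated and 43.7% ± 0.94 stimulated (SD, n = 3 libraries each, exact permutation p = 0.1, the smallest possible). Random sets of 25 autosomal genes with shares of 10% to 90% reached such a median in 0.05% of 10000 draws, a pool matched neither on share nor on reads. Sets drawn from the 30 autosomal genes nearest to each in share and reads reached it in 0.05% of draws, with a median gap in share of 5.51 points, and in 0.180% with more weight on the share and a gap of 1.83 points. Such a median was thus rare among autosomal genes matched that closely. The draws treat genes as independent, though some of the 25 are neighbours and all come from the same 6 libraries. They therefore do not measure chance between libraries. Over the 24 of these genes with both levels the median log2 change was 0.35 on the cast X, where 13 were higher (7 rose and 5 fell past the edgeR test), and -0.45 on the mus X, against 0.04 and -0.76 with library sizes alone. A relative gain of transcripts from the inactive X at genes that already escape is a candidate explanation, and lower expression from the active X may contribute, with the part of each left open by the scaling. Markers of B cells, myeloid cells and NK cells were also lower after stimulation, and the part of a changed mix of cells was not tested. Strain and silencing are confounded at these genes, since the inactive X is the castaneus X in every library. Whether called genes within 2 Mb of Xist rise more than the others stays open, with a mean log2 odds ratio of 1.21 for 5 near genes, all higher, against a mean of 0.56 and a median of 0.27 for 25 others, 21 of them higher (permutation p over genes = 0.119, two-sided). The near genes are few, and Gm38020 lies within Ftx.

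A run of 5 adjacent X-linked genes was read mostly from cast between 134489370 and 134607060, made up of Gm16410 (100%), Btk (99.1%), Rpl36a (100%), Gla (99.6%) and Hnrnph2 (90.1%), in reads summed over the 6 libraries. The genes on either side, Drp2 and Armcx4, had 0 cast reads of 84 and 555. Random orders of the 490 X-linked genes with at least 20 allelic reads gave a run this long with p = 3e-04 (permutation, 10000 draws), so chance placement is argued against. Rpl36a had 54 allelic reads at 56.8 RPKM unstimulated, 0.0044 of the reads expected from its RPKM, and Hnrnph2 and Btk had 0.0300 and 0.235, against a median of 0.709 for coding X-linked genes. Gla and Gm16410 had 0.302 and 0.558. The flanking Armcx4 and Drp2 had 0.359 and 0.792, so a low ratio was not confined to the run. A stretch of the mus X whose reads were lost in allele assignment is a candidate explanation, so the cast shares of these genes, Gla and Hnrnph2 among the called ones, may not reflect the inactive X.

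With 3 against 3 libraries there are 10 splits, too few to exclude chance by their share. Counting the real split, 1 split gave as many changed genes for the diploid comparison (10642, against 0 in the highest other split), for cast shares on the X (11 against 1) and on autosomes (1300 against 0), and for levels on the cast X (46 against 0) and on the mus X (282 against 0). For the gene lists 4 splits gave as many (11 in the real split, 14 in the highest other), so camera's preset correlation calls lists in splits that mix the groups, and for the X-linked set 7 splits gave as small a p (0.285 in the real split, 0.0696 in the lowest other). The replicate numbers pair the libraries, and the real split parts all 3 pairs, as do 3 of the other splits, while the remaining 6 part 1 pair. Among the former the highest counts were again 0, 1, 0, 0 and 0 for genes and 14 for lists, and the lowest p of the X-linked set was 0.0905.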
